A study of Mus musculus with 6 samples.

How the data were processed

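Expression was measured by sequencing polyadenylated RNA from 6 cultures of mouse (C57BL/6) whole bone marrow that had been transduced at day 0 with a retrovirus carrying the BCR-ABL p185 oncogene and a yellow fluorescent protein marker, and grown in vitro for 14 days. Per the labels, the cells were transformed pro-B acute lymphoblastic leukaemia cells that were wild type (wt) or homozygous for a deletion of zinc finger 1 or zinc finger 4 of the transcription factor Ikaros, with 2 biological replicates in each of the 3 groups. The groups are called wt, ZnF1 mutant and ZnF4 mutant. The labels do not say that transduced cells were sorted from the rest of the marrow.

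The deposited values are RPKM (reads scaled to transcript length in kilobases and to the reads of the library) for each RefSeq transcript, per the file headers, written to 1 decimal with 0.1 as the smallest value above 0. The submitters' processing notes name TopHat, bedtools and the mouse build mm9, without versions. How reads shared by overlapping transcripts or by near-identical copies were counted, and whether strand was used, is not given in the sources used here. Levels of overlapping genes (H19 and Mir675, Igf2 and its antisense transcript, Dlx1 and its antisense transcript) and of genes with near-identical copies are therefore uncertain. Gapdh, a glycolytic enzyme with many pseudogene copies, was listed at only 0.9 to 1.9 RPKM in the 6 libraries. The depth of the libraries is unknown, because rounding of the RPKM values hides the step that 1 read makes, so no counting interval is given. The sum of RPKM was 287007 to 345766 per library. RPKM multiplied by transcript length in kilobases summed to 0.812 to 0.889 of the reads to which RPKM is scaled, and 10582 to 11119 genes had at least 1 RPKM.

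The 26531 transcript rows were summed to 22099 genes by symbol, of which 3305 had several rows. In the 1629 genes with several rows and over 5 RPKM, the lower rows were small, with a median of 3.23% of the highest row. A total of 40 rows had symbols that a spreadsheet had turned into numbers, and 39 of these were restored through their RefSeq accession. There was 1 row without a gene, which was left out, and 3 genes of the lists below were not found under their symbol or synonym.

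Genes with at least 1 RPKM in at least 2 libraries were tested, 11345 in all. The test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(RPKM + 1), with all 6 libraries in 1 fit of 3 group means, tested in both directions, and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. The fit had 3 residual degrees of freedom and 2.32 prior degrees of freedom. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. With 2 libraries in a group, p-values measure the spread between the libraries of a group in this experiment. In this fit that spread includes the difference between replicate 1 and replicate 2 libraries that the 3 groups share, which is described below. On simulated data built on the 11345 genes for ZnF4 mutant against wt (20 runs, 100 genes changed by 2-fold and 100 by 4-fold), the fit recovered 17.4% of the genes changed by 2-fold and 87.8% of those changed by 4-fold, and 5.73% of its calls were false. With the replicate number as a block the shares were 97.6% and 99.4%, and 7.51% of calls were false. Each fit was run on data simulated from its own spread, with the replicate difference only in the data of the block fit. The shares therefore do not compare the 2 fits on the same data.

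The labels number the replicates 1 and 2 in each group. Deviations of same-numbered libraries from their group means were correlated across genes at 0.5 for wt and ZnF1 mutant, 0.754 for wt and ZnF4 mutant and 0.715 for ZnF1 mutant and ZnF4 mutant. Same-numbered libraries were thus alike beyond their group, but the main fit leaves this pairing out. The fit with the replicate number as a block (2 residual and 3.06 prior degrees of freedom) is given beside the counts of called genes and of list members past the threshold over all genes, where it moved the count by over 1.5 times, and beside each list call that it changed.

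Gene lists fixed before the data were examined were tested with camera from limma with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 24 lists with at least 5 tested members. They covered B lineage identity, pre-B cell receptor signalling, V(D)J recombination, later B cell stages, stem and progenitor genes, adhesion, DNA replication, mitosis, cell cycle inhibitors, MYC and ribosome biogenesis, glycolysis, targets of STAT5, ERK, p53 and Notch signalling, the BCL2 family, interferon response and histones without polyadenylation. Since polyadenylated RNA was sequenced, levels of these histones may depend on the selection of RNA as well as on the cells. Other lists held markers of T and NK cells, myeloid cells, erythroid cells and megakaryocytes, mast cells and basophils, stroma and endothelium, and plasma cells. Some genes stand in several lists, such as Il2ra, Myc, Btg2, Cdkn1a and Bcl2l1, so the list results are not independent of each other. In the same simulated data, a list of 30 genes shifted by 0.5 (log2) had an unadjusted camera p under 0.05 in 20 of 20 runs, and a list of 30 unchanged genes in 1 of 20. The adjusted threshold used for list calls was not simulated. Genes were simulated as independent, so these rates do not cover lists whose members vary together. No list call of any comparison held with a correlation estimated from the data, with or without the replicate block. The fry test, which asks whether a list moves on balance in 1 direction, called 0 lists in each comparison without the block. With the block it called 6 lists for ZnF1 mutant against wt, 0 for ZnF4 mutant against wt and 15 between the mutants.

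Genes were named by a rule fixed before the data were examined: Ikzf1, then the 10 largest rises and 10 largest falls in each comparison among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the libraries of the 2 groups, leaving out unnamed gene models, and, for each list described, up to 4 tested members with the lowest p. Where fewer than 3 genes qualified in a direction, the 5 with the lowest p were given as values only. Not all of these list members are named in the text, and those named were picked from them after their values were seen. Of the genes with the largest changes, 1 is not reported here. Marker genes given per library (S100a8, S100a9, Col1a1, Sparc, Lyz2, Apoe, Cd74, H2-Ab1 and H2-Aa) were chosen after their values were seen. The alternatives tried were other pseudocounts, filters, scalings and variance settings, fits of 4 libraries, the replicate block, each library left out in turn, a threshold of 0.1 and other list tests. Alternatives chosen after the data had been seen were the highest transcript row per gene, each transcript row on its own, a fit without wt replicate 1 and ZnF1 mutant replicate 2, and the estimated correlation and fry with the replicate block. Fits with libraries left out had no replicate block, so the replicate difference enters the values of a group with 1 library. They also had fewer residual degrees of freedom than the main fit, so a call can end although the fold change stays. Without wt replicate 1 and ZnF1 mutant replicate 2, ZnF1 mutant replicate 1 is set against wt replicate 2. Sequence properties of transcripts came from the mouse GRCm38 reference, which is not the build of the deposited values, so no coordinates are given and only gene names and neighbour order were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.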

Results

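The data were RPKM values of RefSeq transcripts from 6 libraries of BCR-ABL transformed mouse pro-B cells after 14 days of culture, 2 each from wt, ZnF1 mutant and ZnF4 mutant marrow. BCR-ABL p185 is an oncogenic fusion kinase, and Ikaros, encoded by Ikzf1, is a zinc finger transcription factor of lymphoid cells that acts as a tumour suppressor in this leukaemia. The comparisons ask how the loss of zinc finger 1 or of zinc finger 4 alters expression in cells transformed by the same oncogene. The 10 most abundant genes took 4.15% to 5.42% of the summed RPKM in each library.

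Ikzf1 was transcribed in all 6 libraries. Its mean was 87.6 ± 2.33 RPKM (SD, n = 2) in wt, 109 ± 10.7 in the ZnF1 mutant and 179 ± 12.7 in the ZnF4 mutant. It rose in the ZnF4 mutant by 1.02 (log2, SE 0.16, limma adjusted p = 0.045). The value in the ZnF1 mutant against wt was 0.31 (adjusted p = 0.67), and in the ZnF4 against the ZnF1 mutant 0.71 (adjusted p = 0.074, or 0.0084 with the replicate block). The alleles lack single zinc finger exons, so the level summed over the gene does not check the labels. The call in the ZnF4 mutant was lost when any 1 of the 6 libraries was left out, although the log2 fold change stayed at 0.95 to 1.1. Those fits have 1 library in a group and fewer residual degrees of freedom. With the replicate block and all 6 libraries, the limma adjusted p in the ZnF4 mutant against wt was 0.0049.

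Transcripts of other marrow cells differed between libraries. The granulocyte genes S100a8 and S100a9 stood at 199.8 and 193.2 RPKM in wt replicate 1 and at 741.9 and 455.9 in ZnF1 mutant replicate 2, against 0.2 and 0.1 in wt replicate 2 and 1.7 and 0 in ZnF1 mutant replicate 1. In ZnF4 mutant replicates 1 and 2, S100a8 stood at 3.3 and 24.4 RPKM. The macrophage gene Lyz2 was at 357.7 and 426 RPKM in the ZnF1 mutant libraries, 102.2 and 177.8 in wt and 119.2 and 148 in the ZnF4 mutant. The stromal gene Col1a1 was highest in ZnF1 mutant replicate 1, at 28 RPKM against 2 to 8.8 in the other libraries.

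**Figure D1:**
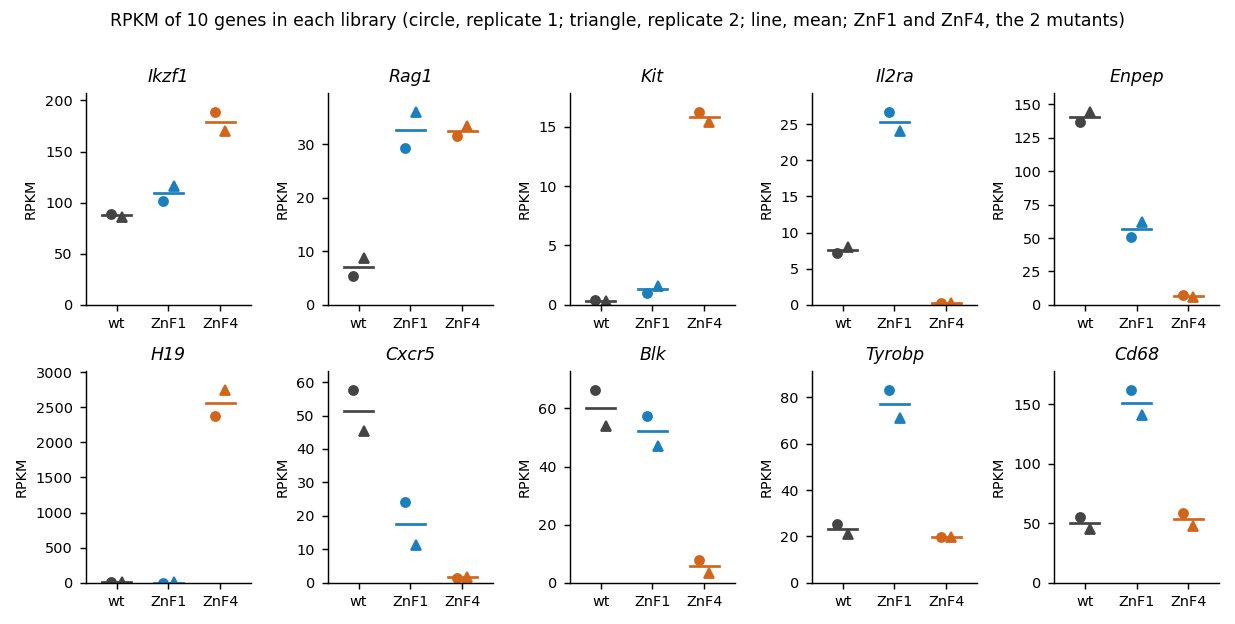
RPKM (linear axis from 0) of 10 genes in each of the 6 libraries, by group, where circles are replicate 1, triangles replicate 2 and lines the mean of the pair. Ikzf1, Kit and H19 were highest in the ZnF4 mutant, Il2ra, Tyrobp and Cd68 in the ZnF1 mutant, and Enpep in wt.

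The first comparison asks what the loss of zinc finger 1 changed. Among the genes with the lowest p, Fcgr2b, an inhibitory Fc receptor, stood at 55.8 ± 2.97 RPKM (SD, n = 2) in the ZnF1 mutant against 16.2 ± 0.919 in wt, and Il2ra, the interleukin 2 receptor alpha chain, at 25.3 ± 1.84 against 7.55 ± 0.636. Emb, an adhesion protein of the basigin family, stood at 28.4 against 9.8 RPKM, the sphingosine phosphate receptor S1pr3 at 7.25 against 0.9 and the sterol hydroxylase Cyp27a1 at 2.6 against 0.2. Lower values were found for Thy1, a surface glycoprotein, at 0.55 ± 0.354 against 11.4 ± 2.12, for the kinase gene Camk2b at 0.05 against 6.1, and for Arpp21 at 2.25 against 15.6. Pde9a, a cyclic GMP phosphodiesterase, stood at 0.35 against 4.45 RPKM and Ica1 at 0.9 against 4.3. Each of these 10 genes had a limma adjusted p of 0.092, and an adjusted p of 0.003 to 0.0059 with the replicate block.

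No gene passed the threshold in this comparison with limma without the replicate block (0 of 11345). There 1281 genes had an unadjusted limma p under 0.05 and the lowest adjusted p was 0.0923. With the replicate block 1502 genes were called, 1175 higher and 327 lower. The count at an adjusted p of 0.1 was 136, 111 higher and 25 lower.

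Genes of later B cell stages rose as a group in the ZnF1 mutant, with 20 of 25 tested members higher and a median log2 fold change of 0.69 (camera adjusted p = 2.58e-05, but adjusted p = 0.307 with an estimated correlation). No member passed over all genes tested, and 8 higher and 1 lower passed adjusted over the list alone. Over all genes with the block, 10 were higher and 1 lower, among them the 4 given next. Il2ra differed by 1.62, the costimulatory gene Cd86 by 1.13, the sphingosine phosphate receptor S1pr1 by 1.7 and the chemokine receptor Ccr7 by 1.53. The list holds genes of class II antigen presentation, which macrophages also express. Of these, the invariant chain gene Cd74 stood at 1160.8 and 524.8 RPKM in the ZnF1 mutant and 193.8 and 104.9 in wt, H2-Ab1 at 35.9 and 32.4 against 40.1 and 24.1, and H2-Aa at 5.5 and 12.6 against 4.7 and 1.2. The myeloid list had a median of 1.24 in the same comparison, and without a filter on low values the later B median was 0.35.

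Pre-B cell receptor signalling genes rose as a group, with 14 of 16 higher and a median of 0.26 (camera adjusted p = 0.0211, adjusted p = 0.621 with an estimated correlation). The count adjusted over the list alone was 1, and 0 over all genes, or 4 higher with the replicate block. The kinase Lyn, which myeloid cells also express, was at 48.1 ± 2.4 RPKM against 27.1 ± 0.636, and the receptor component Cd79b at 654.4 against 418 (adjusted p = 0.1 and 0.26, or 0.0082 and 0.03 with the block). The list call ended without a filter on low values (median 0.21, adjusted p = 0.209) and without wt replicate 2, where the median was 0 (adjusted p = 0.218). It also ended without the pair of libraries with most granulocyte transcripts, where the median was larger, at 0.6. That fit sets ZnF1 mutant replicate 1 against wt replicate 2, so its median also holds the replicate difference. With single libraries left out, the medians were 0 to 0.51. In the same libraries the myeloid and stromal lists had medians of 1.24 and 1.21. Within the V(D)J recombination list, which did not pass as a group (camera adjusted p = 0.723, median −0.05, mean 0.12), Rag1, which cuts antigen receptor genes, stood at 32.5 RPKM against 7.05 and Rag2 at 14.8 against 6.5 (adjusted p = 0.092 and 0.24, or 0.0052 and 0.018 with the block). Over all genes 0 of its 15 tested members passed, or 3 higher and 1 lower with the block, and 1 was higher adjusted over the list alone.

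Adhesion genes rose as a group, with 30 of 37 higher and a median of 0.56 (camera adjusted p = 3.37e-08, adjusted p = 0.307 with an estimated correlation). Over all genes 0 passed, or 18 higher and 1 lower with the replicate block, and 14 higher and 1 lower passed adjusted over the list alone. The focal adhesion kinase Ptk2 differed by 1.23, the tetraspanin Cd9 by 1.08 and the actin crosslinker Actn1 by 1.76. Target genes of ERK signalling, both feedback genes and other induced genes, also rose as a group (18 of 22 higher, median 0.55, camera adjusted p = 0.00122, adjusted p = 0.58 with an estimated correlation). Over all genes 0 members passed the threshold and 0 adjusted over the list alone, or 10 higher over all genes with the block. Their lowest p-values belonged to Spry1 at 1.34 and Fosl1 at 1.09. These 2 genes, Ptk2, Cd9 and Actn1 had adjusted p of 0.0053 to 0.02 with the block. The ERK list call ended without wt replicate 2 (median 0.22, adjusted p = 0.0621). The medians leaving out single libraries were 0.22 to 0.94 for the ERK list and 0.26 to 0.68 for adhesion. Both groups moved with myeloid and stromal transcripts, such as Sparc, a matrix gene, at 87 and 27.7 RPKM in the ZnF1 mutant and 22.3 and 17.1 in wt.

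Proliferation genes fell as groups. DNA replication genes were lower in 32 of 36 cases with a median of −0.13 (camera adjusted p = 0.00214), mitotic genes in 38 of 38 with a median of −0.21 (adjusted p = 9.5e-05), and MYC and ribosome biogenesis genes in 29 of 30 with a median of −0.21 (adjusted p = 0.000119). With an estimated correlation the adjusted p was 0.307 for each. Glycolysis genes fell too, with 18 of 21 lower and a median of −0.23 (camera adjusted p = 0.00214, adjusted p = 0.486 with an estimated correlation), as did histone genes, with 17 of 20 lower and a median of −0.36 (adjusted p = 0.000988, and adjusted p = 0.307 with an estimated correlation). In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. With the replicate block 1 replication, 2 mitotic, 2 MYC and ribosome biogenesis, 5 glycolysis and 3 histone genes were lower over all genes. Single members were Cdk1, a mitotic kinase, at 43.2 RPKM against 50.2, the nucleolar gene Ncl at 211.7 against 307.4 and the glycolytic enzyme Pfkl at 25.1 against 36.3 (adjusted p = 0.89, 0.74 and 0.28, or 0.16, 0.028 and 0.024 with the block). Without the pair of libraries with most granulocyte transcripts, the calls of the replication, MYC and glycolysis lists ended, with medians of 0.06, −0.04 and 0.16. That fit sets ZnF1 mutant replicate 1 against wt replicate 2, so these medians also hold the replicate difference. Leaving out ZnF1 mutant replicate 1 ended the calls of the mitotic and histone lists (medians of −0.12 and −0.15, adjusted p = 0.0955 and 0.144), and leaving out ZnF1 mutant replicate 2 that of glycolysis (median −0.04, adjusted p = 0.0931). The histone call also ended among genes with at least 5 RPKM (median −0.31, adjusted p = 0.213). Leaving out single libraries gave medians of −0.17 to −0.04 for replication, −0.25 to −0.12 for mitosis, −0.28 to −0.12 for MYC and ribosome biogenesis, −0.4 to −0.01 for glycolysis and −0.55 to −0.15 for histones. These falls stood beside higher myeloid and stromal transcript levels in the same libraries.

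Myeloid genes rose as a group in the ZnF1 mutant, with 23 of 25 higher and a median of 1.24 (camera adjusted p = 1.93e-09, adjusted p = 0.307 with an estimated correlation). Stromal and endothelial genes rose with 18 of 19 higher and a median of 1.21 (camera adjusted p = 5e-09, adjusted p = 0.307 with an estimated correlation). Over all genes 0 members of either list passed, and adjusted over the list alone 12 and 10 were higher and 0 and 1 lower. The block gave 13 and 11 higher and 0 and 1 lower over all genes, among them the 4 given next. Cd68, a macrophage lysosomal protein, was at 151.2 ± 14.6 RPKM against 50.1 ± 7.14, the adaptor Tyrobp at 77 against 23.2, the growth factor receptor Csf1r at 34.9 against 13.1, and the fibronectin gene Fn1 at 73 against 23.3. Leaving out single libraries gave medians of 0.82 to 1.67 for the myeloid and 0.48 to 2.1 for the stromal and endothelial list. The replicate block added calls of STAT5 and p53 targets, both higher (adjusted p = 0.0216 and 0.0269, but adjusted p = 0.442 and 0.5 with the block and an estimated correlation). The lists that did not pass were B lineage identity (adjusted p = 0.871), stem and progenitor (0.871), cell cycle inhibitors (0.102), STAT5 (0.068) and p53 targets (0.068), the BCL2 family (0.446), interferon response (0.208), Notch targets (0.723), T and NK cells (0.163), erythroid cells (0.406), mast cells (0.487) and plasma cells (0.37).

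**Figure D2:**
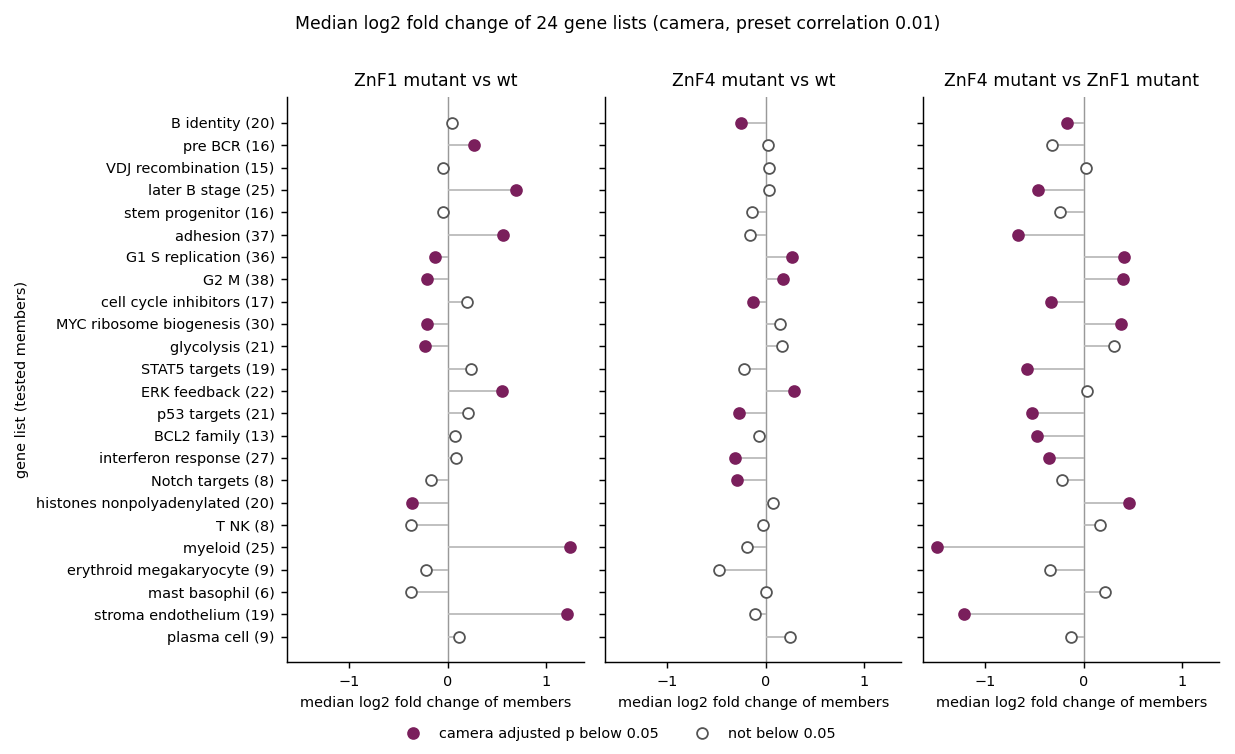
Median log2 fold change of the tested members of 24 gene lists (horizontal axis) in each of the 3 comparisons, where filled points passed camera at an adjusted p under 0.05 with a preset correlation and open points did not. Replication and mitosis lists lie below 0 in the ZnF1 mutant and above 0 in the ZnF4 mutant. Without the pair of libraries with most granulocyte transcripts, which leaves different replicate numbers to compare, replication in the ZnF1 mutant was at 0.06. No filled point holds with an estimated correlation.

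The second comparison asks what the loss of zinc finger 4 changed. The imprinted noncoding gene H19 rose from 15.5 ± 3.11 to 2554 ± 261 RPKM (SD, n = 2), a log2 fold change of 7.28 (SE 0.78, limma adjusted p = 0.02), and its neighbour Igf2, a fetal growth factor, rose from 0.25 ± 0.212 to 172 ± 115. Kit, the stem cell factor receptor of early progenitors, rose from 0.35 ± 0.0707 to 15.8 ± 0.566 RPKM (3.64, SE 0.18, adjusted p = 0.0049). Enpep, the BP-1 antigen of pre-B cells, fell by 4.24 (SE 0.17, adjusted p = 0.0039) from 140.4 ± 5.16 to 6.5 ± 0.707 RPKM, and Cxcr5, a chemokine receptor of mature B cells, fell by 4.33 (SE 0.36, adjusted p = 0.0094).

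Of 11345 genes, 309 passed the threshold with limma, 162 higher and 147 lower, and all 309 were also among the 1809 genes called with the replicate block (910 higher, 899 lower). The count was 16 without wt replicate 1, 8 without wt replicate 2, 90 and 119 without ZnF1 mutant replicate 1 or 2, and 0 without either ZnF4 mutant library or without the pair of libraries with most granulocyte transcripts. It was 176 among genes with at least 5 RPKM and 131 in a fit of the 4 libraries. Fits with fewer libraries have fewer residual degrees of freedom than the 3 of the main fit, so lost power alone can lower these counts. The counts therefore do not show that the calls came from the libraries left out.

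Other large rises were those of Mir675 (7.2), which lies within H19, the ephrin ligand Efna1 (4.15), the homeobox gene Hoxb7 (3.64), the transcriptional regulator Lmo1 (3.49), Hs3st2 (3.48), Smpdl3b (3.47) and the GTPase Gem (3.36), with adjusted p from 0.0039 to 0.018. Other large falls were those of the glycine cleavage enzyme Gldc (−5.16), Tmem59l (−5.13), the cadherin-related gene Cdhr2 (−4.71), the adhesion gene Mpzl2 (−4.34), the homeobox gene Dlx1 (−3.83), the matricellular gene Nov (−3.62) and the Fc receptor-like gene Fcrl6 (−3.61), with adjusted p from 0.0039 to 0.022. The rule for named genes was met by 97 rises and 102 falls, and by 3 and 4 unnamed gene models.

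B lineage identity genes fell as a group, with 13 of 20 lower and a median of −0.25 (camera adjusted p = 0.0286, adjusted p = 0.837 with an estimated correlation). Over all genes 1 rose and 2 fell, or 1 and 7 with the replicate block, and adjusted over the list alone 2 rose and 4 fell. The kinase Blk fell by 3.27 (60.1 to 5.7 RPKM, adjusted p = 0.021) and the surface receptor Cd72 fell by 1.01 (adjusted p = 0.045), while Rag1 rose by 2.09 (7.05 to 32.5 RPKM, adjusted p = 0.023). The identity call ended without ZnF4 mutant replicate 2 (median 0.05) or wt replicate 1 (median −0.08). These fits have no replicate block, so both medians also hold the replicate difference. The call also ended without the pair of libraries with most granulocyte transcripts (median −0.08, adjusted p = 0.194) and with camera on ranks (adjusted p = 0.107). Among V(D)J recombination genes, which did not pass as a group (adjusted p = 0.512, median 0.04, mean −0.04), the ligase Lig4 fell by 1.29 (adjusted p = 0.029). Of the 15 tested, 1 rose and 1 fell over all genes, and 2 and 3 both with the block and adjusted over the list alone.

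In the later B cell stage list, which did not pass (adjusted p = 0.429), 2 of 25 genes rose and 4 fell over all genes, or 4 and 5 with the replicate block, and 3 rose and 4 fell adjusted over the list alone. Il2ra fell by 2.77 (7.55 to 0.25 RPKM) and the adhesion receptor Cd2 fell by 2.68, while Cd180, a Toll-like receptor relative, rose by 1.56. In the stem and progenitor list, which did not pass (adjusted p = 0.0957), Kit rose, and Enpep and the MYC family gene Mycn fell. The value of Mycn was −2.19 (limma adjusted p = 0.029). Enpep is the pre-B cell antigen named above, so its fall is not a fall of an early progenitor gene. With the block 2 members of this list rose and 6 fell, and adjusted over the list alone 2 rose and 5 fell. In the adhesion list (adjusted p = 0.418), 3 of 37 rose and 1 fell over all genes, or 6 and 10 with the block, and 3 and 2 adjusted over the list alone. Ptk2 rose by 2.73 (1.75 to 17.3 RPKM), the catenins Ctnnd1 by 2.2 and Ctnna1 by 0.94, and Cd47 fell by 1.3.

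DNA replication genes rose as a group, with 34 of 36 higher and a median of 0.27 (camera adjusted p = 0.000325, adjusted p = 0.717 with an estimated correlation), and mitotic genes with 35 of 38 higher and a median of 0.18 (camera adjusted p = 0.0288, adjusted p = 0.837 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone (0 and 0). Over all genes, 10 replication genes and 1 mitotic gene rose with the replicate block. Cell cycle inhibitors fell as a group, with 13 of 17 lower and a median of −0.13 (adjusted p = 0.0286, adjusted p = 0.837 with an estimated correlation), and 0 members passed either way, or 5 fell over all genes with the block. The cyclin Ccne1 was at 40.5 RPKM against 31.3, the inhibitor Cdkn1a at 50.5 against 124, and the antiproliferative gene Btg1 at 3.4 against 8.65 (adjusted p = 0.43, 0.49 and 0.099, or 0.039, 0.007 and 0.0025 with the block). The mitotic call ended without wt replicate 1 (adjusted p = 0.564), ZnF4 mutant replicate 2 (0.436) or the pair of libraries with most granulocyte transcripts (0.707), with medians of 0.15, 0.12 and 0.15. The inhibitor call ended under the same 3 alternatives (adjusted p = 0.0995, 0.338 and 0.0963), although the medians of −0.17, −0.14 and −0.16 were no smaller in size, and among genes with at least 5 RPKM (median −0.11, adjusted p = 0.0526). With single libraries left out, the medians were 0.12 to 0.29 for mitosis and −0.39 to −0.12 for inhibitors. MYC and ribosome biogenesis genes passed camera with the replicate block but not in the main fit (adjusted p = 0.0957 without and 0.0381 with the block). With the block and an estimated correlation the camera adjusted p was 0.885.

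Target genes of ERK signalling rose as a group, with 16 of 22 higher and a median of 0.29 (camera adjusted p = 0.0286, adjusted p = 0.837 with an estimated correlation). Of these, 2 rose both over all genes and adjusted over the list alone, or 6 over all genes with the replicate block. The 2 were Spry4, an inhibitor of receptor tyrosine kinase signalling, by 1.6 (adjusted p = 0.022), and the phosphatase Dusp4, by 2.07 (adjusted p = 0.037). Targets of p53 fell as a group, with 16 of 21 lower and a median of −0.27 (camera adjusted p = 0.00117, adjusted p = 0.717 with an estimated correlation), 0 over all genes, or 9 with the block, and 2 adjusted over the list alone. Interferon response genes fell with 23 of 27 lower and a median of −0.31 (adjusted p = 0.000325, adjusted p = 0.837 with an estimated correlation), and Notch targets with 6 of 8 lower and a median of −0.29 (adjusted p = 0.0286, adjusted p = 0.837 with an estimated correlation). The RNA sensor Ddx58 fell by 1.11 (adjusted p = 0.034), the only interferon gene of 27 past the threshold over all genes. With the block 2 rose and 4 fell, and adjusted over the list alone 1 rose and 4 fell. Il2ra and Heyl, a transcriptional repressor (fell by 2.51, adjusted p = 0.027), were the 2 Notch targets past it, both over all genes and adjusted over the list alone. With the block 3 Notch targets fell. In the BCL2 family, which did not pass (adjusted p = 0.159), Bcl2, an inhibitor of apoptosis, fell by 1.45 (adjusted p = 0.037), the only 1 of 13 over all genes. With the block 1 rose and 3 fell, and adjusted over the list alone 2 fell. The ERK call ended without wt replicate 2 (median −0.05) or ZnF4 mutant replicate 1 (median 0.03). These fits have no replicate block, so both medians also hold the replicate difference. The p53 call ended without ZnF4 mutant replicate 2 (median −0.13, adjusted p = 0.0858). The interferon and Notch calls ended without wt replicate 1 (medians of −0.1 and −0.07, adjusted p = 0.111 for both) or the pair of libraries with most granulocyte transcripts (medians of −0.05 and −0.07, adjusted p = 0.149 and 0.0963). The Notch call also ended without ZnF4 mutant replicate 2, where the median was 0 (adjusted p = 0.198), and with camera on ranks (adjusted p = 0.192). Leaving out single libraries gave medians of −0.05 to 0.6 for ERK, −0.47 to −0.13 for p53, −0.58 to −0.1 for interferon and −0.7 to 0 for Notch.

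The third comparison sets the mutants against each other. Il2ra stood at 0.25 ± 0.0707 RPKM (SD, n = 2) in the ZnF4 mutant and 25.3 ± 1.84 in the ZnF1 mutant, a log2 fold change of −4.39 (SE 0.16, limma adjusted p = 0.0031), and Nov at 2.25 ± 1.06 and 75.6 ± 3.96 (−4.6, SE 0.25, adjusted p = 0.0075). Higher in the ZnF4 mutant were H19 (9.59, adjusted p = 0.011), Igf2 (6.59), the troponin gene Tnni2 (4.02), a neighbour of H19, and Ndrg1, a stress response gene (3.95). The count of called genes was 609 of 11345, 183 higher and 426 lower in the ZnF4 mutant, and all 609 were among the 3979 called with the replicate block (1803 higher, 2176 lower). It was 306 and 261 without wt replicate 1 or 2, 1 and 4 without ZnF1 mutant replicate 1 or 2, 0 and 4 without ZnF4 mutant replicate 1 or 2, and 0 without the pair of libraries with most granulocyte transcripts. It was 323 among genes with at least 5 RPKM and 324 in a fit of the 4 libraries. Here too, lost power alone can lower the counts of fits with fewer libraries.

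Further rises in the ZnF4 against the ZnF1 mutant were those of Mir675 (9.17), Efna1 (3.69), Hoxb7 (3.51), Rbpms (3.31), Mdfi (3.18) and Fetub (3.1). Further falls were those of Cdhr2 (−4.63), Gldc (−4.09), the TNF family ligand Tnfsf8 (−4.02), the receptor Gpr171 (−3.75), Mpzl2 (−3.61), Stxbp6 (−3.59), Arl5c (−3.53) and the nucleic acid sensor Zbp1 (−3.41). The rule was met by 113 rises and 276 falls, and by 6 and 8 unnamed gene models.

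**Figure D3:**
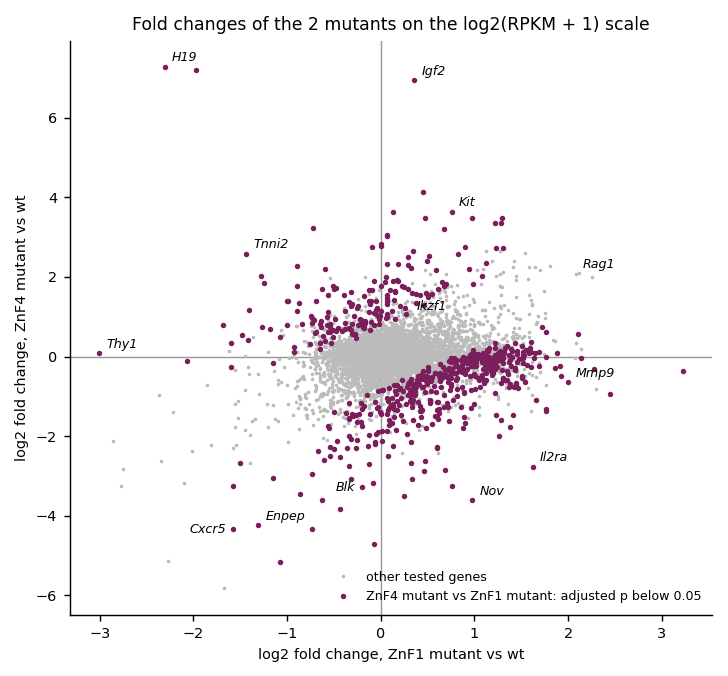
Log2 fold change against wt of the ZnF4 mutant (vertical) and the ZnF1 mutant (horizontal), on the log2(RPKM + 1) scale, for 11345 genes, with the 609 genes past the threshold between the mutants in purple. Il2ra and Nov lie right of and below 0, and H19 and Tnni2 left of and above 0.

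Proliferation genes stood higher in the ZnF4 than in the ZnF1 mutant as groups. DNA replication genes rose with 35 of 36 higher and a median of 0.41 (camera adjusted p = 5.17e-07), mitotic genes with 37 of 38 higher and a median of 0.4 (adjusted p = 4.98e-06), MYC and ribosome biogenesis genes with 30 of 30 higher and a median of 0.38 (adjusted p = 2.83e-05), and histone genes with 18 of 20 higher and a median of 0.46 (adjusted p = 0.00259). With an estimated correlation the adjusted p was 0.296 for each. In the first 3 lists 0 members passed over all genes and 0 adjusted over the list alone, and among histones 1 rose, Hist1h2ab, both ways. With the replicate block 30 replication, 29 mitotic, 16 MYC and ribosome biogenesis and 6 histone genes rose over all genes, and 1 replication and 1 histone gene fell. Cdk1 stood at 61.5 RPKM against 43.2, and Myc, a driver of cell growth, at 262.2 against 167.4 (adjusted p = 0.13 and 0.21, or 0.011 and 0.044 with the block). The histone call ended without ZnF1 mutant replicate 1 (median 0.26, adjusted p = 0.0929) and among genes with at least 5 RPKM (median 0.49, adjusted p = 0.116). Myeloid and stromal transcripts were lower in the ZnF4 mutant libraries at the same time.

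Targets of p53 fell as a group, with 19 of 21 lower and a median of −0.53 (camera adjusted p = 5.18e-05, adjusted p = 0.296 with an estimated correlation), 4 over all genes, or 12 with the replicate block, and 7 adjusted over the list alone. The 4 were Btg2, an antiproliferative gene (−1.67), the TNF receptor family gene Eda2r (−1.41), the polo-like kinase Plk2 (−1.18) and Trp53inp1 (−1.32). Cell cycle inhibitors fell with 14 of 17 lower and a median of −0.33 (adjusted p = 0.00231, adjusted p = 0.345 with an estimated correlation), 2 over all genes and 3 adjusted over the list alone, among them Cdkn2b (−0.89). With the block 1 inhibitor rose and 9 fell. STAT5 targets fell with 13 of 19 lower and a median of −0.57 (adjusted p = 0.00764, adjusted p = 0.605 with an estimated correlation). Over all genes 1 of them rose, Cdk6, and 2 fell, Il2ra and the kinase Pim1 (−1.77). With the block 3 rose and 11 fell, and adjusted over the list alone 1 rose and 6 fell. The BCL2 family fell with 10 of 13 lower and a median of −0.47 (adjusted p = 0.0314, adjusted p = 0.605 with an estimated correlation), 1 over all genes, Bcl2 (−1.21), and 6 adjusted over the list alone. With the block 1 member of that family rose and 7 fell. Leaving out ZnF4 mutant replicate 2 ended the STAT5 and BCL2 calls (medians of −0.41 and −0.1, adjusted p = 0.0611 and 0.169), and leaving out ZnF1 mutant replicate 1 that of BCL2 (median −0.4, adjusted p = 0.129). The STAT5 median was −0.95 to −0.27 leaving out single libraries. In the same comparison the myeloid and stromal lists had medians of −1.49 and −1.21.

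Later B cell stage genes fell as a group, with 17 of 25 lower and a median of −0.46 (camera adjusted p = 0.00121, adjusted p = 0.4 with an estimated correlation). Over all genes 1 rose and 8 fell, and adjusted over the list alone 2 and 9, with values of −3.01 for Cd2, −3.1 for the lymphoid surface gene Ly6d and −2.75 for Cxcr5. B lineage identity genes fell with 15 of 20 lower and a median of −0.17 (adjusted p = 0.0287, adjusted p = 0.605 with an estimated correlation), 1 higher and 2 lower over all genes, or 1 and 8 with the replicate block, and 1 and 5 adjusted over the list alone. Blk fell by 3.08, and Cd22, an inhibitory receptor of B cells, rose by 2.02. Interferon response genes fell with 24 of 27 lower and a median of −0.35 (adjusted p = 0.00024, adjusted p = 0.546 with an estimated correlation), 4 over all genes and 6 adjusted over the list alone, among them the guanylate binding proteins Gbp2 (−3.14) and Gbp3 (−2.26). With the block 1 interferon gene rose and 9 fell. The later B and identity calls ended without a filter on low values (medians of −0.21 and −0.17, adjusted p = 0.0513 and 0.0669), and the identity call without ZnF4 mutant replicate 2 (median −0.02, adjusted p = 0.311). The medians leaving out single libraries were −0.95 to −0.42 for later B stages, −0.49 to −0.02 for identity and −0.54 to −0.2 for interferon. Of the genes shared with macrophages, Cd74 stood at 115.6 and 47.2 RPKM in the ZnF4 mutant against 1160.8 and 524.8 in the ZnF1 mutant, H2-Ab1 at 55.5 and 22 against 35.9 and 32.4, and H2-Aa at 28.9 and 8.4 against 5.5 and 12.6. The myeloid list had a median of −1.49 in the same comparison.

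Adhesion genes fell as a group, with 27 of 37 lower and a median of −0.67 (camera adjusted p = 7.08e-05, adjusted p = 0.422 with an estimated correlation), 3 higher and 8 lower over all genes, or 5 and 22 with the replicate block, and 3 and 14 adjusted over the list alone. Pecam1 fell by 1.23 and Cd97 fell by 1.63, while Ptk2 rose by 1.5. Myeloid genes fell with 25 of 25 lower and a median of −1.49 (adjusted p = 2.2e-07, adjusted p = 0.296 with an estimated correlation), 7 over all genes, or 12 with the block, and 10 adjusted over the list alone, among them Tyrobp (−1.92), Cd68 (−1.49) and the protease Mmp9 (−2.64). Stromal and endothelial genes fell with 17 of 19 lower and a median of −1.21 (adjusted p = 4.98e-06, adjusted p = 0.4 with an estimated correlation), 2 higher and 3 lower over all genes, or 2 and 15 with the block, and 2 and 14 adjusted over the list alone. Thy1 rose by 3.1 and the endothelial cadherin Cdh5 by 1.28, and the collagen Col1a2 fell by 2.07. Leaving out single libraries gave medians of −1.74 to −0.97 for the myeloid and −2.57 to −1.14 for the stromal and endothelial list. The replicate block added calls of pre-B cell receptor signalling (lower) and glycolysis (higher), with adjusted p = 0.029 and 0.0412, but adjusted p = 0.554 and 0.448 with the block and an estimated correlation.

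Changes shared by both mutants against wt could not be listed at the threshold, since 0 genes were called in both, with 0 called in the ZnF1 mutant (limma, 1281 at an unadjusted p under 0.05). With the replicate block 366 genes were called in the same direction in both, 244 higher and 122 lower, and 168 in opposite directions. Independent lists of those lengths would share 94.2 higher and 25.9 lower genes. In 100 simulated pairs of unchanged groups against the same wt libraries, 0.19 genes were shared on average and 2 at most. Those groups had on average only 0.47 higher and 0.34 lower calls in place of the ZnF1 mutant, and 0.36 and 0.48 in place of the ZnF4 mutant. So few calls could hardly overlap, and the simulated overlap does not measure how many of the 366 genes come from the shared wt libraries. Fold changes of the 2 mutants were correlated across genes at 0.135, and genes are not independent replicates. Simulated groups without any change gave 0.498 from the shared wt libraries alone. Changes in 1 mutant alone lower this value, so the gap does not show opposite changes. The covariance was 0.028, against a simulated 0.0482 without the block and 0.0124 with it. The wt libraries are too few to be split, so part of any overlap may come from them. Without wt replicate 1 or 2 the correlation was 0.342 or 0.351, and 0.364 without the pair of libraries with most granulocyte transcripts. These fits keep 1 wt library, so the replicate difference enters the fold changes of both mutants.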

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

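Of the tests below, those of stromal markers and of granulocyte genes were chosen only after the result was seen. For the tests of neighbouring genes and of shared copies, the demand that a bound be cleared by more than the spread was also added after their values were seen, and by the bound alone the shared-copy difference of 0.07 would have counted against that explanation.

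A group of genes stood on opposite sides of both wt libraries in the 2 mutants, and differed between the mutants by the direct limma test. Of 11345 genes, 864 lay on opposite sides, where 100 simulations of unchanged groups that kept the replicate difference gave 60 on average and 80 at most. Genes were simulated as independent, so the 60 and 80 do not cover genes that vary together between libraries. The simulations held no change in either mutant, and a change in 1 mutant alone would also raise the count. The excess therefore does not show that both mutants moved. The direct test was passed by 294 of these, 30 of them named here. Higher in the ZnF4 than in the ZnF1 mutant (log2 fold change) were H19 by 9.59, Mir675 by 9.17, Tnni2 by 4.02, Ndrg1 by 3.95, Rbpms by 3.31, Mdfi by 3.18, Fetub by 3.1, Car2 by 2.47, Ica1 by 2.03, Cd22 by 2.02, Pfkl by 1.01, Hist1h2ab by 0.84 and Cdk6 by 0.73. The value in the ZnF4 against the ZnF1 mutant was −4.6 for Nov, −4.39 for Il2ra, −4.02 for Tnfsf8, −3.59 for Stxbp6, −3.53 for Arl5c, −3.14 for Gbp2, −3.01 for Cd2, −2.64 for Mmp9, −2.26 for Gbp3 and −2.07 for Col1a2. It was −1.92 for Tyrobp, −1.77 for Pim1, −1.63 for Cd97, −1.41 for Eda2r, −1.23 for Pecam1, −0.9 for Lyn and −0.89 for Cdkn2b. The difference from wt was small on 1 side for some, with values in the ZnF4 mutant against wt of −0.09 for Lyn, 0.19 for Hist1h2ab and −0.23 for Tyrobp. Tyrobp and Mmp9 belong to the myeloid list and Col1a2 and Pecam1 to the stromal and endothelial list, both higher in the ZnF1 mutant. The replication and mitosis lists were called lower in the ZnF1 mutant and higher in the ZnF4 mutant, with medians of 0.41 and 0.4 between the mutants. The opposite directions did not hold throughout: without wt replicate 1 and ZnF1 mutant replicate 2 the replication call in the ZnF1 mutant ended and its median was 0.06. There ZnF1 mutant replicate 1 is set against wt replicate 2, so that median cannot be told apart from the replicate difference. In the ZnF1 mutant the mitotic call ended without ZnF1 mutant replicate 1 (median −0.12). In the ZnF4 mutant it ended without wt replicate 1, ZnF4 mutant replicate 2 or the pair of libraries with most granulocyte transcripts (medians of 0.15, 0.12 and 0.15). With an estimated correlation their adjusted p was 0.307 in the ZnF1 mutant, 0.717 and 0.837 in the ZnF4 mutant and 0.296 between the mutants, where the myeloid and stromal lists had medians of −1.49 and −1.21.

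H19 and Igf2 were far higher in both ZnF4 mutant libraries. Stromal cells, which can express both genes, are argued against by the 19 tested stroma and endothelium markers, whose median log2 fold change was −0.11 with a half-width of 0.088 (9 higher, 10 lower). Examples of the lower markers were Col1a2 at 3.8 and 3.2 RPKM against 5.6 and 7 in wt and Sparc at 17.6 and 9.2 against 22.3 and 17.1. Pecam1 of the same list stood at 9.9 and 9.4 against 18.6 and 18.3. However, 3 markers were higher in both ZnF4 mutant libraries than in both wt libraries. They were Fn1, Kdr and the endothelial gene Cdh5 (2.1 and 1.3 RPKM, listed at 0 in wt, limma adjusted p = 0.027). A change of the whole chromosomal neighbourhood is argued against too, since the 5 tested genes among 10 on each side had a median of 0.04, at the 50.4 percentile of random windows (18.6 to 73.9 leaving out 1 gene), although Lsp1 rose by 1.54 and Tnni2, left out because its value had been seen, by 2.58. A local change that takes in Tnni2 and Lsp1, endothelial cells alone, and an effect of the ZnF4 deletion itself, stay open and were not tested.

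Monocyte and macrophage genes were higher in both ZnF1 mutant libraries. Granulocytes carried over into the cultures are argued against as the source, since 6 of 6 granulocyte genes were under 2 RPKM in ZnF1 mutant replicate 1, where other myeloid genes stood at a median of 2.13 times the higher wt library. A larger share of macrophages may account for the pattern, as a second list of macrophage genes had a median log2 fold change of 1.05 with 29 of 34 members higher in both libraries, against a median of 0.18 in the ZnF4 mutant. None of that list's genes is in another list, and the abundant macrophage genes Lyz2 and Apoe stood at 357.7 and 426 and at 161.2 and 85 RPKM in the ZnF1 mutant. Expression of these genes by the transformed cells themselves stays open, because the labels do not say whether the transduced cells were sorted from the rest.

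Replicate 1 and replicate 2 libraries differed alike in all 3 groups, with 158 genes at least 2-fold apart in each group, such as Tpt1 at 47.1 and 0.8 RPKM in wt. GC content of the transcripts may account for much of this, with Spearman's rho of 0.71 across 11208 genes, which are not independent replicates. Transcript length gave a rho of −0.27, between the bounds set beforehand, and genes with over 50% of their 36-base stretches shared with other genes differed from genes with none by 0.07 (bootstrap SD 0.035), so both stay open. A difference in library preparation between the replicate numbers is a candidate source that the labels do not record, and no biological explanation was tested.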

How the results depend on the processing

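The tests chosen after the result was seen were the fits without wt replicate 1 and ZnF1 mutant replicate 2 (the 2 libraries with most granulocyte transcripts), with the highest transcript row per gene, and with each transcript row on its own, and fry and the estimated correlation with the replicate block. The replicate block raised the counts of called genes to 1502 (ZnF1 mutant against wt), 1809 (ZnF4 mutant against wt) and 3979 (between the mutants), and a threshold of 0.1 to 136, 502 and 1094. The first count was 0 under all other alternatives run. A filter of 5 RPKM gave 176 and 323 for the last 2 comparisons, with fewer genes tested, and a fit of the 4 libraries compared 131 and 324, with fewer samples. Without the 2 granulocyte-rich libraries, where wt and the ZnF1 mutant keep 1 library each and are assumed to vary like the rest, both counts were 0. Leaving out single libraries gave 0 to 119 and 0 to 306. The estimated correlation, with or without the block, and fry without it called 0 lists in each comparison, and fry with the block called 6, 0 and 15. ZnF1 mutant against wt had 7 higher and 2 lower list calls without the granulocyte-rich libraries, against 6 and 5 with them, and ZnF4 mutant against wt had 3 list calls without them and 3 to 12 leaving out single libraries. Genes called in both mutants numbered 366 with the block and 38 at 0.1, and the correlation of fold changes was 0.364 without the granulocyte-rich libraries and 0.082 to 0.351 leaving out single libraries. Ikzf1 in the ZnF4 mutant kept its direction and lost its call at 1.02 without a filter, with the 5 RPKM filter, with quantile normalization and with 4 libraries, at 0.99 with median-of-ratios scaling, at 1.05 without the granulocyte-rich libraries, and at 0.95 to 1.1 leaving out single libraries (adjusted p = 0.0522 to 0.594 over these alternatives). Between the mutants Ikzf1 gained its call with the block at 0.71. Reversals of the tested direction, which for camera is relative to all other genes, were found only among values that had not passed: Tyms in the ZnF1 mutant without the granulocyte-rich libraries (0.14), the V(D)J list in the ZnF1 mutant leaving out single libraries (−0.21 to 0.04) and with fry, with or without the block (−0.05), and in the ZnF4 mutant leaving out single libraries (−0.18 to 0.23), the later B list in the ZnF4 mutant without a filter (0.12) and leaving out single libraries (−0.43 to 0.31), and the adhesion list in the ZnF4 mutant with fry (−0.16). Of 87 calls of genes chosen by the naming rule or singled out, named or not, 0 kept their side of the threshold under every alternative and 0 reversed, and 520 of 1546 values lost the call. Some fits with libraries left out, which have fewer residual degrees of freedom, ended every gene call. No gene could therefore keep its call throughout, whatever its own values. Of 33 list calls, 0 held everywhere, which the estimated correlation fixed by itself, and 156 of 759 values lost the call. The direction given by the test reversed in 0 of them, but the median changed sign in 4, each with the call lost: replication (0.06) and glycolysis (0.16) in the ZnF1 mutant without the granulocyte-rich libraries, and in the ZnF4 mutant ERK without wt replicate 2 (−0.05) and B identity without ZnF4 mutant replicate 2 (0.05). In 2 others it came to 0, pre-B cell receptor signalling in the ZnF1 mutant without wt replicate 2 and Notch in the ZnF4 mutant without ZnF4 mutant replicate 2. Leaving out 1 library moved the median of 25 of the 33 lists by over 1.5 times. The fits with libraries left out have no block, so the replicate difference enters these medians and changes of sign. The block gave a call to 89 of 198 values of such genes and ended none (0), changed list calls as stated beside them, and scalings moved the median of all genes by less than 0.1. The depth is unknown, so what it limits could not be measured. Where no cause is given, the cause was not tested.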

Other observations

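The values in this part were chosen after they were seen, and no explanation was tested for them. Car2, a carbonic anhydrase of the erythroid marker list, stood at 167.8 ± 14 RPKM (SD, n = 2) in wt, 52.6 ± 15.6 in the ZnF1 mutant and 289.6 ± 30.8 in the ZnF4 mutant, and was higher in the ZnF4 than in the ZnF1 mutant by 2.47 (limma adjusted p = 0.014). Lat, an adaptor of T cell receptor signalling, was at 19.1 RPKM in wt, 1.7 in the ZnF1 mutant and 3.4 in the ZnF4 mutant (adjusted p = 0.098 and 0.1 against wt, or 0.0041 and 0.0016 with the replicate block). The T and NK cell list as a whole passed in neither comparison against wt (camera adjusted p = 0.163 and 0.295).

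The Y-linked genes Eif2s3y (26.5 to 46.5 RPKM) and Ddx3y (9.2 to 18.7 RPKM) were expressed in all 6 libraries, and Xist, which is expressed from the inactive X chromosome, was at 0.4 RPKM or less. Abl1, part of which is in the transduced fusion, stood at 56.3 to 85.2 RPKM and Bcr at 22 to 47.6.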
